A study of Mus musculus with 9 samples.

How the data were processed

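Mouse brain RNA was sequenced in 9 libraries, 3 per group: control, MCAO and MCAO with hypidone hydrochloride at 5 mg/kg for 7 days. Groups come from the sample labels, and replicate numbers from the sample titles. Total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal kit, per the labels' protocols. The authors deposited raw counts per gene symbol, FPKM values that scale each count by its library total and a fixed length per gene, and a table of their own comparisons with a ratio (fold change) and a q-value per gene. The submitters' processing notes name the mm10 genome build and DESeq2, without a role or version. The aligner, the counting tool and the strand setting are not given in the sources used here, so reads of overlapping or near-identical genes could be divided in unknown ways. All 9 columns of the count table matched a sample by title.

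Genes were kept with edgeR's filterByExpr, which left 14756 of 18138. Libraries were scaled with TMM, and all 9 entered 1 quasi-likelihood fit (edgeR 4.0.16 in R 4.3.3) with 6 residual degrees of freedom. Each comparison was a two-sided F test with Benjamini-Hochberg adjustment at 0.05, and standard errors are the log2 fold change divided by the root of F. CPM values are TMM-scaled. Gene lists, 43 in all and fixed before the data were examined, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 5 genes were tested, which left 40 lists. Camera with an estimated correlation and fry were the alternatives.

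The genes named were chosen by a rule written at the same time: the 6 largest changes in each direction among called, non-overlapping genes with an average log2 CPM of at least 1 and a regular symbol; up to 3 members with the lowest p from the 8 called lists with the lowest p; the inflammation, glial and drug-target genes Il1b, Tnf, Il6, Gfap, Aif1, Htr1a and Slc6a4; and, for hypidone against MCAO, the 5 genes with the lowest adjusted p among those called in the opposite direction with MCAO. Other genes, namely Ttr, Ch25h, Elk1, Shank3, Neurod6, Egr3, Egr4, Atf3 and those first named in the observations, were named after their values were seen. Some genes that the rule covers are not reported here. Gene symbols were matched to GENCODE M21 for positions: 14447 of 14756 tested symbols matched 1 gene.

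Alternatives were other scaling (DESeq2 size factors, library totals), other filters (none, CPM of at least 1 in 3 libraries), other tools (DESeq2 1.42.0, limma voom with quality weights, limma on log2 of FPKM plus a pseudocount of 1), a fit of only the groups compared, a minimum fold of 2, a replicate block for control and MCAO, which share title numbers, and leaving out each library in turn. Fits without control 5 beyond the planned ones were added after seeing the data. Chance values for the shared MCAO libraries came from 20 simulated sets of unchanged groups, with genes drawn independently.

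The fit was tested on simulated data of 14756 genes, with 100 genes changed 2-fold, 100 changed 4-fold and 15 genes of a list raised 2-fold. For MCAO against control it recovered 39 of 100 genes changed 2-fold and 86 of 100 changed 4-fold and 11 of the list, with 11 false calls of 147. For hypidone against MCAO it recovered 39, 89 and 6, with 8 false calls of 142, and for hypidone against control 50, 90 and 6, with 4 of 150. Each simulated gene had the same dispersion in all groups, and genes were drawn independently. The real biological coefficient of variation was 41.7% within MCAO, 29.4% within control and 14.5% within the hypidone group. These rates of recovery and false calls therefore need not hold for the real data.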

Results

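RNA was sequenced from mouse brain tissue in 3 groups of 3 libraries: control animals, animals with middle cerebral artery occlusion (MCAO, a surgical model of ischaemic stroke), and MCAO animals given hypidone hydrochloride at 5 mg/kg for 7 days. The brain region, the hemisphere and whether control animals had sham surgery are not given in the sources used here. The treatment labels give a dose and a number of days only for the hypidone group, and no vehicle or time for control or MCAO. Each library held between 32075682 (control 4) and 37325027 (MCAO 4) gene counts over 18138 genes, and 14756 genes had enough counts to be tested. Libraries are named by their group and the number in their title. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

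MCAO libraries lay apart from all others and from each other. The first principal component held 47.3% of the variance of log2 CPM (counts scaled to a common library size) and ran from control 4 at -42.4 to MCAO 5 at 103, with MCAO 6 at 64.4 and MCAO 4 the nearest of its group to the others. The 3 hypidone libraries lay between -31.0 and -13.0 on it, and the controls between -42.4 and -22.7. The biological coefficient of variation was 41.7% within MCAO, 29.4% within control and 14.5% within the hypidone group. Pearson correlations of log2 CPM across genes were 0.984 to 0.989 between hypidone libraries and 0.915 to 0.971 between MCAO libraries. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 8.92.

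**Figure D1:**
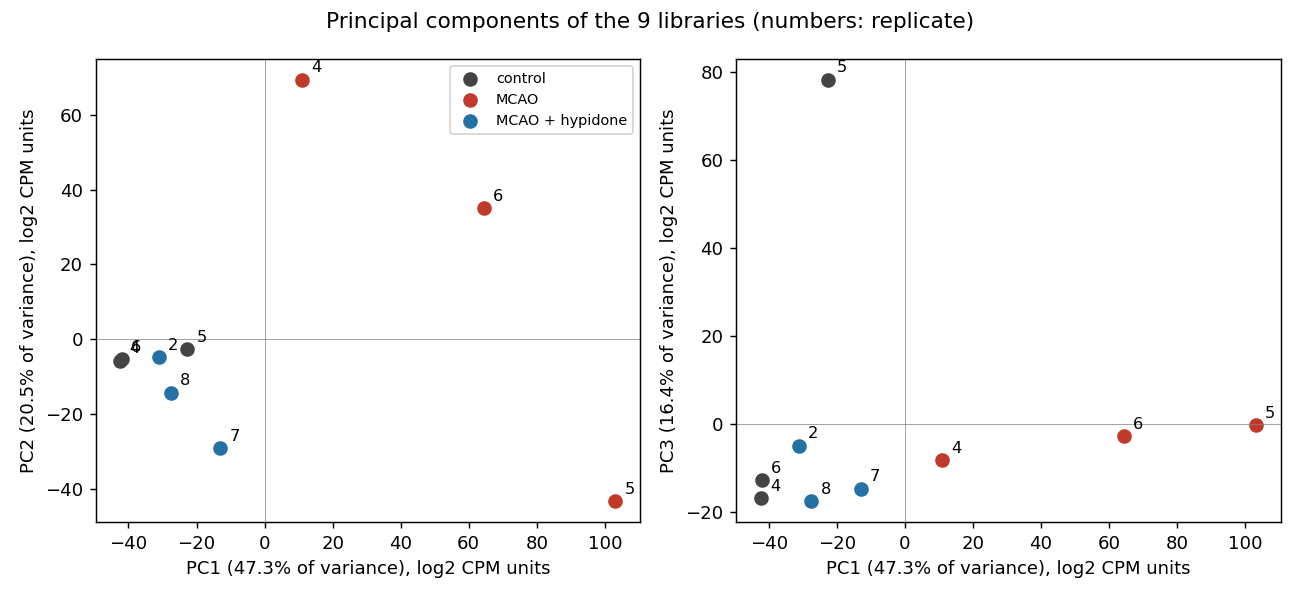
Principal component scores of the 9 libraries, in log2 CPM units, with the share of variance on each axis; point colour gives the group and the number beside a point its replicate. MCAO 5 is farthest out on the first component at 103, and control 5 stands alone on the third at 78.4.

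Control 5 differed from control 4 and control 6 in genes of the hippocampus and in Ttr. Its mean log2 CPM over the 9 tested genes of the hippocampal neuron list was 5.79, against at most 2.52 in any other library. The transthyretin gene Ttr, abundant in choroid plexus, was at 153 CPM in control 5 and at most 8.16 CPM elsewhere. Carbonic anhydrase gene Car12, Fibcd1 and the lactase gene Lct, which the fixed rule names for MCAO against control, stood at 44.2, 152 and 50.1 CPM in control 5. Their values in control 4 were 3.48, 9.84 and 1.18 CPM. For MCAO against control they had log2 fold changes of -5.26 ± 1.02, -4.19 ± 1.07 and -4.96 ± 1.47, and without control 5 of -3.19, -1.66 and -0.92. The call of Lct was lost without control 5 (adjusted p = 0.251) and without MCAO 4, 5 or 6 (adjusted p between 0.0766 and 0.122), and that of Fibcd1 without MCAO 5 or 6 (adjusted p = 0.0578 and 0.0952).

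MCAO against control asks what the occlusion changed in brain tissue. Genes of glucocorticoid response (9 of 11) and cell death (8 of 15) rose, 14 of 20 activated microglia, 13 of 15 reactive astrocyte, 10 of 16 complement and 8 of 16 matrix genes rose very unevenly between libraries, and 12 of 16 genes of sterol synthesis fell. These lists had an adjusted p of 0.568 to 0.671 with an estimated correlation. Pnpla2, the main triglyceride lipase of fat droplets, rose from 25.1 ± 1.51 to 126 ± 13.9 CPM (SD, n = 3), a log2 fold change of 2.32 ± 0.13 (SE). The p53-induced stress gene Trp53inp1 rose by 2.27 ± 0.17 and the cell cycle inhibitor gene Cdkn1a by 3.16 ± 0.37. The activity-regulated synaptic gene Arc fell by 3.41 ± 0.62 on the log2 scale, from 425 ± 216 to 40.0 ± 31.0 CPM, and the neuropeptide gene Cort fell by 4.33 ± 0.50. Tcap fell by 3.68 ± 0.77, or 3.04 without control 4, a call lost without MCAO 6 (adjusted p = 0.0577).

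Of 14756 genes, 1567 were higher and 1448 lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), with 869 and 531 of them changed at least 2-fold. Values of the groups did not overlap for 33.5% of genes, where chance gives 10% of them. These counts moved with single libraries: 543 higher and 700 lower without control 4, 480 and 613 without control 6, 717 and 594 without MCAO 6, 2357 and 1918 without MCAO 4, and, through the shared spread, 960 and 944 without hypidone 7 and 991 and 985 without hypidone 8. A fit of only these groups gave 345 higher and 337 lower genes. It ended the calls of 16 of the 36 named genes called in this comparison, namely Car12, Fibcd1, Lct, Tcap, Chil3, Msr1, Spp1, Cd68, Ctsd, Trem2, C1qb, C1qc, C3ar1, Col4a1, Bcl2l11 and Gfap, with an adjusted p between 0.0507 and 0.112. The authors' deposited comparison listed 1057 genes up and 555 down by at least 2-fold at a q under 0.05, and of the 1567 and 1448 genes 1412 and 1266 passed its q threshold alone in the same direction.

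Glucocorticoid-induced genes rose as a group: 9 of the 11 rose and none fell (10 adjusted over the list alone), with a median log2 fold change of 1.75 (camera adjusted p = 9.94e-07). The lipid droplet gene Plin4 rose by 4.07 ± 0.56, the metallothionein gene Mt2 by 2.18 ± 0.33 and the kinase gene Sgk1 by 1.47 ± 0.18. The p53 and apoptosis list had 8 of 15 genes higher (10 adjusted over the list alone, adjusted p = 3.79e-05), among them Bcl2l11, which encodes a pro-apoptotic protein, at 1.78 ± 0.34. Sterol synthesis genes fell: 12 of 16 were lower (13 adjusted over the list alone), with a median fold of 0.499 (adjusted p = 9.21e-07). Idi1 fell by 1.70 ± 0.19, Cyp51 by 1.41 ± 0.18 and Dhcr7 by 1.06 ± 0.13, all enzymes of that pathway. With an estimated correlation the adjusted p was 0.568 for the glucocorticoid list and 0.671 for the other 2 lists.

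Activated microglia genes rose, 14 of 20 (17 adjusted over the list alone, median 2.36, camera adjusted p = 1.17e-05), and so did 13 of 15 reactive astrocyte genes (13 adjusted over the list alone, median 3.58, adjusted p = 3.79e-05). The lysosomal genes Cd68 and Ctsd rose by 3.54 ± 0.68 and 2.54 ± 0.51, and the microglial receptor gene Trem2 by 2.31 ± 0.45. Osteopontin gene Spp1 rose by 7.20 ± 1.69, with 4961 CPM in MCAO 5, 295 in MCAO 6 and 23.3 in MCAO 4 against 10.8 to 13.2 in control. The astrocyte genes Osmr, Steap4 and Aspg rose by 2.80 ± 0.48, 5.04 ± 0.95 and 4.38 ± 0.78. Complement had 10 of 16 genes higher (12 adjusted over the list alone, adjusted p = 7.63e-05), with C1qb, C1qc and the receptor gene C3ar1 up by 2.58 ± 0.56, 2.59 ± 0.54 and 4.32 ± 0.91. The Toll-like receptor and NF-kB list had 8 of 19 higher (13 adjusted over the list alone, adjusted p = 4.48e-05), including Tlr2 at 4.05 ± 0.33, Tlr7 at 3.80 ± 0.43 and Rela at 0.90 ± 0.13. Matrix and fibroblast genes were higher in 8 of 16 cases (12 adjusted over the list alone, adjusted p = 0.000254), with Col4a1 at 2.56 ± 0.54 and Sparc at 1.51 ± 0.29. Each of these lists had an adjusted p of 0.671 with an estimated correlation. Calls were lost without control 4 for C1qb, C3ar1 and Col4a1 and without control 6 for Ctsd, C1qb, C1qc and C3ar1, with an adjusted p between 0.0504 and 0.0634. Without MCAO 5 the log2 fold changes were 2.36 for Cd68, 1.76 for Ctsd, 1.61 for Trem2, 3.75 for Spp1, 3.90 for Steap4, 3.69 for Aspg, 1.62 for C1qb, 1.78 for C1qc, 2.59 for C3ar1 and 1.64 for Col4a1.

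Macrophage-related genes Chil3, Lilr4b, Lilrb4a and Msr1 and the transglutaminase gene Tgm1 had the largest increases beside Spp1 under the fixed rule, with log2 fold changes between 7.28 for Chil3 and 8.11 ± 1.44 for Lilrb4a. Their mean control levels were at most 0.143 CPM, where a fitted fold depends on the prior count. MCAO 5 carried most of these increases: in MCAO 4, 5 and 6 Msr1 was at 0.313, 81.0 and 8.29 CPM and Chil3 at 1.11, 41.7 and 5.00. Without MCAO 5 the log2 fold changes were 4.91 for Chil3, 4.87 for Msr1, 6.42 for Lilr4b, 6.32 for Lilrb4a and 6.66 for Tgm1. Lilr4b and Lilrb4a are closely related copies. Calls were lost without control 4 for Chil3, Lilr4b, Msr1, Spp1 and Tgm1, with an adjusted p between 0.0553 and 0.0800. Without control 6 they were lost for Lilr4b, Msr1, Spp1 and Tgm1, with an adjusted p between 0.0613 and 0.0821, and without MCAO 6 for Lilr4b (adjusted p = 0.0515).

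Other immune and vascular lists rose by fewer members: cytokines and chemokines 6 of 13, NRF2 targets 4 of 12, proliferation 3 of 16, endothelium 5 of 14, monocytes and macrophages 6 of 14, the inflammasome 4 of 11, neutrophils 2 of 8 and resting astrocytes 4 of 14 (camera adjusted p between 0.000749 and 0.0271). Adjusted over the list alone, the counts were 6, 6, 13, 5, 9, 5, 4 and 4. For proliferation and macrophages the adjusted p was 0.706 with an estimated correlation, and for the rest 0.671. Without MCAO 5, which held the highest levels of the activated microglia, reactive astrocyte, complement and macrophage lists, 9 lists were called higher and 3 lower in place of 15 and 6. Lists of cytokines, Toll-like receptors, activated microglia, complement, both astrocyte states, matrix, p53 and glucocorticoid response stayed higher, and the homeostatic microglia list became lower at an adjusted p of 0.0135, with 7 of 13 genes lower and 2 higher. With all libraries that list had 2 genes higher and 1 lower.

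Neuronal genes were lower as lists with few members past the test: 5 of 15 glutamatergic genes fell (5 adjusted over the list alone, median -0.57, camera adjusted p = 0.00955), 1 of 13 pan-neuronal genes (1 adjusted over the list alone, adjusted p = 0.00856) and 1 of 12 GABAergic genes (1 adjusted over the list alone, adjusted p = 0.0222). The synaptic scaffold gene Shank3 and the transcription factor gene Neurod6, named after their values were seen, fell by 1.06 ± 0.16 and 2.38 ± 0.50. Respiratory chain genes were lower as a list with 1 of 20 past the test (0 adjusted over the list alone, adjusted p = 0.0276). The erythrocyte list was lower at an adjusted p of 0.0134 with 0 of 5 genes past the test (3 adjusted over the list alone). The respiratory chain had an adjusted p of 0.725 with an estimated correlation, and the other 4 lists 0.671. Without MCAO 5 the calls of the neuronal and respiratory chain lists were lost, with an adjusted p of 0.175 for pan-neuronal, 0.121 for glutamatergic, 0.269 for GABAergic and 0.560 for respiratory chain genes. No call was made for the remaining 19 tested lists, whose adjusted p lay between 0.0559 for myelin and 0.714 for interferon response, and hypothalamic, T cell and B cell lists had under 5 tested genes.

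Genes fixed in advance for inflammation, glia and drug targets gave mixed results. Gfap, the astrocyte filament gene, rose by 2.77 ± 0.76 (edgeR adjusted p = 0.0334), from 327 ± 291 to 2232 ± 1419 CPM (SD, n = 3), and this call was lost without control 4, control 6, MCAO 5 or MCAO 6, with an adjusted p between 0.0538 and 0.110. The interleukin gene Il1b had only 135 counts over all libraries and an estimate of 1.34 ± 0.64 (adjusted p = 0.160). Aif1, a microglial gene, had 1.05 ± 0.63 (adjusted p = 0.253) and an opposite sign, -0.30, without MCAO 5. The serotonin receptor gene Htr1a had -1.22 ± 0.41 (adjusted p = 0.0622), or 0.0499 without control 4, and -0.48 without control 5. Tnf, Il6 and the serotonin transporter gene Slc6a4 had 46, 9 and 13 counts in all and were not testable at this depth.

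**Figure D2:**
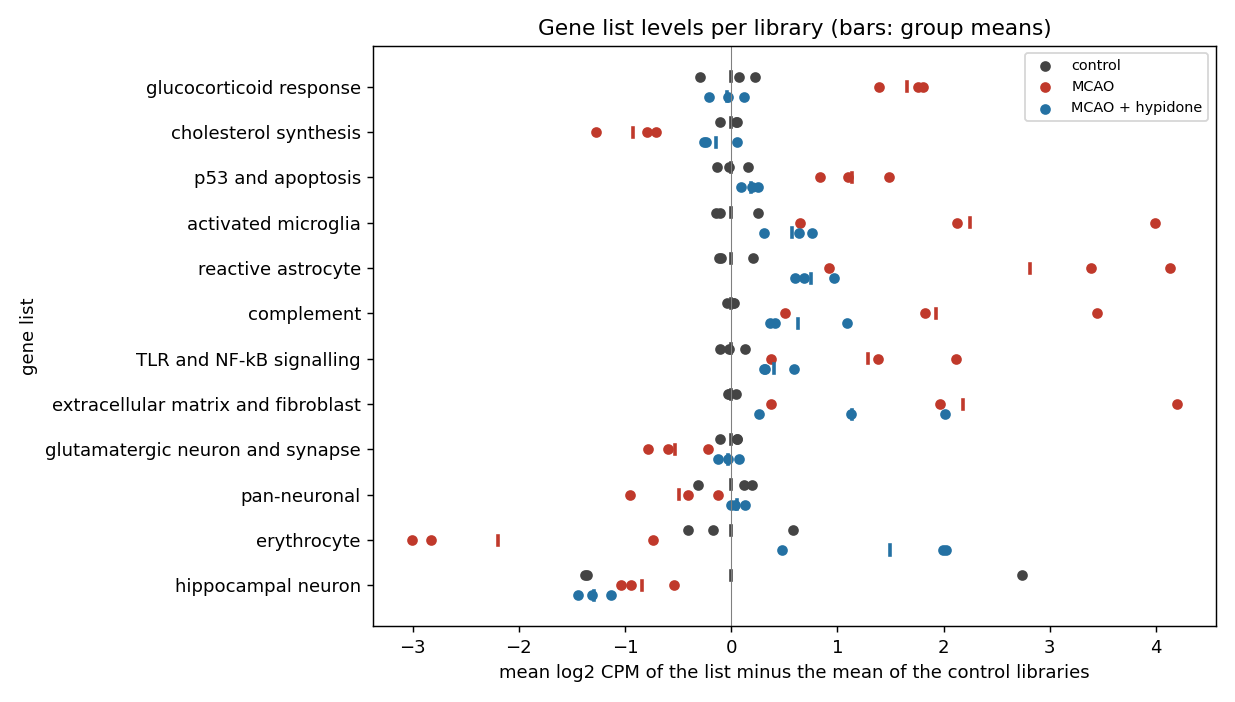
Mean log2 CPM of 12 gene lists in each library, as the difference from the mean of the control libraries; points are libraries, short bars group means, and colours groups. In the glucocorticoid list the MCAO libraries lie at 1.39, 1.76 and 1.81 and the hypidone libraries between -0.21 and 0.12, while in the activated microglia list MCAO runs from 0.65 to 3.99.

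Hypidone against untreated MCAO asks what differed with the drug after the occlusion, in a series whose title names inflammation as its subject. The labels do not say that these groups were matched for vehicle or for time after the occlusion. Such differences cannot be told apart from the drug. Glucocorticoid (8 of 11), cell death (8 of 15), activated microglia (9 of 20) and reactive astrocyte (9 of 15) genes fell, and sterol synthesis (11 of 16) and red cell (5 of 5) genes rose. These lists had an adjusted p of 0.474 to 0.875 with an estimated correlation. In the microglia and astrocyte lists MCAO 4 lay within the range of the drug libraries. Pnpla2 was at 25.9 ± 2.22 CPM with the drug against 126 ± 13.9 without (SD, n = 3), a fall of 2.28 ± 0.13 on the log2 scale. Phyhd1, an oxygenase gene, fell by 1.93 ± 0.15, Trp53inp1 fell by 2.16 ± 0.17, and Pik3ip1, a negative regulator of PI3-kinase, fell by 1.40 ± 0.12. Ankrd34a rose by 1.72 ± 0.13, from 26.1 ± 1.89 to 86.1 ± 0.71 CPM, Arc rose by 3.78 ± 0.63 and Cort by 4.39 ± 0.50.

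With the drug 1215 genes were higher and 1222 lower (edgeR quasi-likelihood test), 481 and 572 of them at least 2-fold. Groups did not overlap for 39.9% of genes, where chance gives 10% of them. Counts were 388 higher and 341 lower without MCAO 6, and between 315 and 350 higher and 233 and 250 lower without any of hypidone 2, 7 or 8. Without MCAO 4 they were 1752 and 2123. The authors' deposited comparison listed 623 genes up and 945 down by at least 2-fold at a q under 0.05, and 1208 and 1220 of the genes called here passed its q threshold alone in the same direction.

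The glucocorticoid list fell in 8 of 11 genes (11 adjusted over the list alone, median -1.70, camera adjusted p = 5.08e-07), with log2 fold changes of -3.96 ± 0.55 for Plin4, -2.39 ± 0.33 for Mt2 and -1.51 ± 0.18 for Sgk1. Sterol synthesis rose in 11 of 16 genes (13 adjusted over the list alone, with 1 lower, median 0.83, adjusted p = 5.01e-06), with Idi1, Cyp51 and the regulator gene Srebf2 up by 1.47 ± 0.19, 1.27 ± 0.18 and 1.14 ± 0.17. The p53 list fell in 8 of 15 genes (9 adjusted over the list alone, adjusted p = 0.000158), with Cdkn1a at -2.60 ± 0.36 and the death receptor gene Tnfrsf10b at -2.97 ± 0.63. Activated microglia genes fell in 9 of 20 cases (16 adjusted over the list alone, median -1.87, adjusted p = 0.000186) and reactive astrocyte genes in 9 of 15 (13 adjusted over the list alone, median -2.65, adjusted p = 0.000919). MCAO 5 and 6 carried both falls. Mean log2 CPM of activated microglia was 4.41, 7.75 and 5.88 in MCAO 4, 5 and 6, against 4.07 to 4.52 with the drug. For reactive astrocytes it was 2.94, 6.15 and 5.41, against 2.62 to 2.99 with the drug. Log2 fold changes were -2.93 ± 0.66 for Cd68, -2.25 ± 0.51 for Ctsd, -1.93 ± 0.44 for Trem2, -2.54 ± 0.47 for Osmr, -3.90 ± 0.96 for Lcn2 and -3.36 ± 0.74 for Aspg. Toll-like receptor and NF-kB genes fell in 4 of 19 cases (5 adjusted over the list alone, camera adjusted p = 0.000919). Among them were Tlr2, Tlr7 and the inhibitor gene Nfkbia, at -3.01 ± 0.31, -3.29 ± 0.42 and -1.36 ± 0.19. Mean log2 CPM of this list was 2.17, 3.91 and 3.18 in MCAO 4, 5 and 6, against 2.10 to 2.39 with the drug, so MCAO 4 lay within the drug range. For the glucocorticoid list the adjusted p was 0.474 with an estimated correlation, and for each other list here 0.875. Calls of Cd68, Osmr, Ctsd, Trem2, Aspg, Lcn2 and Tnfrsf10b were lost without hypidone 7 or 8, those but Osmr also without hypidone 2, and those but Osmr and Cd68 also without MCAO 6, with an adjusted p between 0.0534 and 0.105. Without MCAO 5 the log2 fold changes were -1.74 for Cd68, -1.46 for Ctsd, -1.23 for Trem2 and -2.66 for Aspg, and without MCAO 6 that of Lcn2 was -2.97.

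Haemoglobin genes and Alas2, the first enzyme of haem synthesis in red cells, rose together: all 5 erythrocyte genes rose (5 adjusted over the list alone, median 3.59, adjusted p = 0.000585, or 0.875 with an estimated correlation). Hbb-bs was at 88.7 ± 38.3 CPM with the drug, 7.36 ± 7.81 in MCAO and 34.6 ± 10.3 in control, and Hba-a1 rose by 3.25 ± 0.59. Calls of Hbb-bs and Alas2 were lost without hypidone 7 or 8, with an adjusted p between 0.0526 and 0.0636. These markers of blood moved with the drug group beside all the lists named here.

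Complement fell in 5 of 16 genes, NRF2 targets in 2 of 12, matrix genes in 3 of 16, cytokines in 3 of 13 and resting astrocyte genes in 2 of 14, while pan-neuronal genes rose in 2 of 13 cases, GABAergic in 2 of 12 and glutamatergic in 3 of 15 (camera adjusted p between 0.00429 and 0.0423). Without MCAO 5 the neuronal lists had an adjusted p between 0.185 and 0.234. Adjusted over the list alone, the counts were 8, 5, 3, 4, 2, 2, 5 and 5. In complement and matrix genes MCAO 4, at a mean log2 CPM of 2.90 and 3.16, lay within the range of the drug libraries. That range was 2.75 to 3.48 for complement and 3.04 to 4.79 for matrix genes. Cytokine genes had a mean log2 CPM of -0.40 in MCAO 4, also within the drug range of -1.16 to -0.31. The neurofilament gene Nefl rose by 0.94 ± 0.20 and Tubb3 by 0.89 ± 0.25, while Nefh had 0.74 ± 0.27 (adjusted p = 0.0888). Calls of Nefl and Tubb3 were lost without MCAO 6 or hypidone 2, 7 or 8, with an adjusted p between 0.0502 and 0.131. Immediate early genes were higher as a list (adjusted p = 0.0357), with Arc, Egr3 and Egr4 higher and Atf3 lower of 18 genes (5 higher and 1 lower adjusted over the list alone). The MCAO libraries disagreed in this list, at a mean log2 CPM of 3.54, 3.66 and 6.12 in MCAO 4, 5 and 6, against 5.29 to 6.13 with the drug and 5.07 to 5.69 in control, and its call was lost without MCAO 4, MCAO 5 or hypidone 2 (adjusted p = 0.239, 0.250 and 0.107). Each of these lists had an adjusted p of 0.875 with an estimated correlation. Without MCAO 5 only 7 lists were called: glucocorticoid, p53, activated microglia and resting astrocytes lower, and sterol synthesis, erythrocyte and homeostatic microglia higher. With all libraries the other 24 tested lists were not called, with an adjusted p between 0.0565 for proliferation and 0.842 for interferon response.

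The largest falls under the fixed rule were in A2m, Asb4, Chil3, Col7a1, Lilrb4a and Olfr1033, with log2 fold changes of -4.49 ± 0.78 for Asb4 to -5.34 ± 1.31 for Chil3. The largest rises beside those given were in the nicotinic receptor gene Chrnb3 at 4.67 ± 1.07, Gkn3 at 4.24 ± 0.73, Tcap at 4.23 ± 0.79 and Alas2 at 3.67 ± 0.71. Calls of A2m, Chil3, Col7a1, Lilrb4a, Olfr1033 and Chrnb3 were lost without hypidone 2 or 7, those of the first 4 and Chrnb3 also without hypidone 8, those of A2m, Chil3, Col7a1, Chrnb3 and Tcap without MCAO 6, and that of Col7a1 without MCAO 5, with an adjusted p between 0.0511 and 0.131. Without MCAO 5 the log2 fold changes were -2.70 for Col7a1 in place of -4.66, -2.97 for Chil3, -3.38 for Lilrb4a and -3.34 for Olfr1033, and without MCAO 6 that of Asb4 was -3.74. A fit of only these groups ended the calls of Col7a1 and Tubb3 (adjusted p = 0.0515 and 0.0571). Of the 39 named genes called here, 20 kept the call without each library of the 2 groups in turn.

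Gfap fell by 2.58 ± 0.75 (edgeR adjusted p = 0.0466), a call lost without MCAO 5, MCAO 6 or any hypidone library, with an adjusted p between 0.0703 and 0.154. Il1b had 0.77 ± 0.59 (adjusted p = 0.381), Htr1a 0.45 ± 0.41 (adjusted p = 0.462) and Aif1 -0.87 ± 0.62 (adjusted p = 0.351), which turned to 0.49 without MCAO 5.

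**Figure D3:**
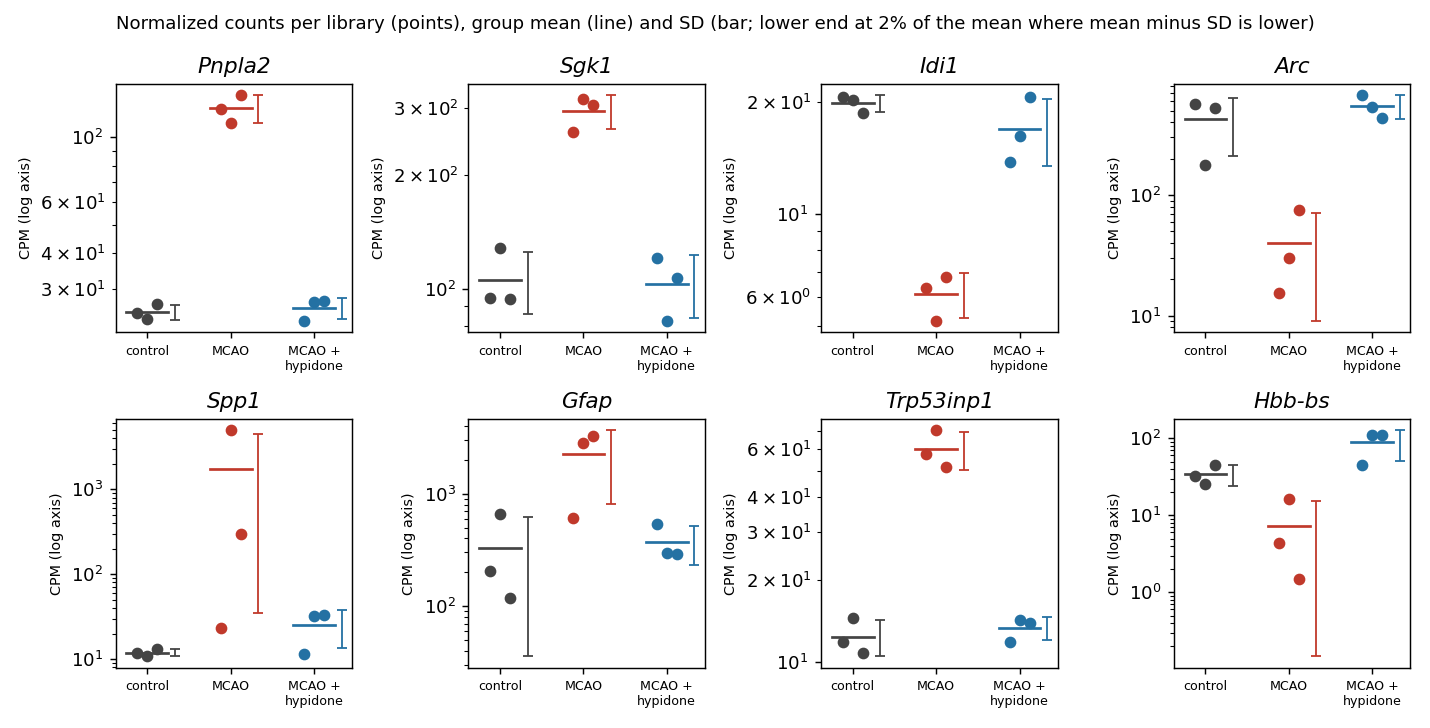
CPM per library on a log axis for 8 named genes, with group means as lines and the SD as a bar whose lower end is drawn at 2% of the mean where the mean minus the SD lies lower. All 3 MCAO libraries lie at 112 CPM or more for Pnpla2 and all other libraries at 27.3 or less, whereas Spp1 runs from 23.3 to 4961 CPM within MCAO.

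Changes with MCAO and with the drug ran mostly in opposite directions, with opposite signs for 89.9% of genes against 76.5% in simulated sets. Of the genes called in both comparisons, 1064 were higher with MCAO and lower with the drug, 1069 were the reverse, and 0 were called in the same direction in both (edgeR). Without control 4 or 6 the opposite calls numbered 1055 and 942 in place of 2133, without MCAO 4 or 6 they numbered 3452 and 693, and without hypidone 2, 7 or 8 they numbered 586, 582 and 541. Independent lists would share 130 and 119 genes. The MCAO libraries enter both comparisons with opposite signs, so chance alone gives opposite values. Fold changes had a covariance across genes of -0.765 and a correlation of -0.90, against -0.145 and -0.71 in 20 simulated sets of unchanged groups, a difference in covariance of -0.621. When the MCAO libraries were divided so that none was used on both sides, the covariance lay between -0.561 and -0.276. Genes are not independent replicates, and part of the overlap may come from the shared libraries. The simulated genes were drawn independently, so these sets do not show how far chance values vary when genes move together.

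Hypidone against control asks how far the treated tissue differed from tissue without occlusion. Lists of neutrophil, macrophage, activated microglia, reactive astrocyte, complement, matrix and red cell genes lay above control and those of myelin and oligodendrocyte precursor genes below, without a single gene past the test, and 0 of the 40 tested lists were called with an estimated correlation (lowest adjusted p = 0.160) or with fry. Without control 5, the library with the highest myelin level, the oligodendrocyte precursor list turned sign and its call was lost. The edgeR quasi-likelihood test called 0 genes, with 131 genes, 0.89% of those tested, at an unadjusted p under 0.05. DESeq2 called 1 gene, Ch25h, with a log2 fold change of 2.26, limma voom called 0, and edgeR on only these groups called 0. Without control 5 that last fit called Elk1 at 1.17, an alternative chosen after seeing the data. The spread was estimated over all 9 libraries, MCAO included, which widens it for these groups. Groups did not overlap for 6.57% of genes, where chance gives 10% of them. Among genes called higher with MCAO the median log2 fold change was 1.15 for MCAO against control and 0.09 for hypidone against control, and among those called lower -0.85 and -0.05, with the control libraries shared.

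Camera called 17 lists higher and 5 lower, without any member past the test over all genes (0 genes by edgeR, 1 by DESeq2 and 0 by limma voom in all). Neutrophil genes had a median of 2.42 (0 of 8 genes past the test, 2 adjusted over the list alone, adjusted p = 9.03e-11), with Retnlg at 3.50 ± 0.97, S100a8 at 2.44 ± 1.01 and S100a9 at 2.43 ± 0.71, whose means with the drug were at most 4.18 CPM. Erythrocyte genes had a median of 1.60 (adjusted p = 6.05e-07, Hba-a1 at 1.60 ± 0.55, Alas2 at 1.73 ± 0.65, Hbb-bt at 1.79 ± 0.81), matrix genes 1.14 (adjusted p = 1.10e-06, Thbs1 at 3.45 ± 1.28, Col1a1 at 2.63 ± 1.26, Col6a1 at 1.38 ± 0.52) and macrophage genes 1.39 (adjusted p = 2.87e-05, Ccr2 at 2.95 ± 1.67, Lyz2 at 2.09 ± 1.18, Mrc1 at 1.29 ± 0.79). Cytokines had 1.23 (camera adjusted p = 2.87e-05), with Ccl4 and Il1b at 2.98 ± 1.09 and 2.11 ± 0.63. Ccl4 was at only 0.0404 ± 0.0204 CPM in control and 0.338 ± 0.391 with the drug, with overlapping groups, so its fold is uncertain. Ccl2, at 0.205 ± 0.180 CPM with the drug, was detected in only 1 of 3 controls, too few counts for a fold. Complement had 0.40 (camera adjusted p = 0.000134), with C2, C1s1 and Serping1 at 1.55 ± 0.55, 1.28 ± 0.63 and 1.23 ± 0.69. Each of these 5 further lists had 0 members past the test adjusted over the list alone. Neutrophils had an adjusted p of 0.160 with an estimated correlation, and the others named here between 0.598 and 0.613. The other higher lists were Toll-like receptors, reactive astrocytes, activated microglia, both antigen presentation lists, endothelium, pericytes, clock genes, proliferation, stress of the endoplasmic reticulum and immediate early genes, with an adjusted p between 0.000338 and 0.0421, or between 0.613 and 0.749 with an estimated correlation.

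Lower lists were myelin at a median of -0.50 (0 of 13, adjusted p = 2.73e-07, with Opalin at -0.67 ± 0.28, Mog at -0.55 ± 0.23 and Mag at -0.51 ± 0.26), hippocampal neurons at -2.65 (0 of 9, with Tdo2, C1ql2 and Spink8 at -3.88 ± 1.28, -6.27 ± 2.06 and -5.87 ± 2.13), sterol synthesis at -0.18, oligodendrocyte precursors at -0.20 and the respiratory chain at -0.07. The last 4 had an adjusted p between 0.000338 and 0.0409. These lists had an adjusted p between 0.613 and 0.749 with an estimated correlation. The remaining 18 tested lists were not called, with an adjusted p between 0.0640 for p53 and 0.959 for neurotrophic genes. Gfap had 0.19 ± 0.71, Aif1 0.18 ± 0.62 and Htr1a -0.77 ± 0.41, none of them past the test. Without control 5 the Gfap value was 1.22, also not called.

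These list calls depended on single libraries: of the 22, camera kept 14 without control 4, 14 without control 5, 15 without hypidone 7, 17 without control 6, 18 without hypidone 2 and 19 without hypidone 8. Without control 5 the calls of hippocampal neurons, oligodendrocyte precursors, antigen presentation by MHC class I, endothelium, pericytes, stress of the endoplasmic reticulum, clock genes and immediate early genes were lost, with an adjusted p between 0.101 and 0.869. The hippocampal median was then 0.19, with C1ql2 at 0.0974, Spink8 at 0.31 and Tdo2 at -0.67, and that of oligodendrocyte precursors 0.0889. Myelin genes had a mean log2 CPM of 7.49 in control 5, 6.42 and 6.82 in controls 4 and 6 and 6.25 to 6.87 with the drug, and without control 5 their median was -0.14 in place of -0.50, with an adjusted p of 0.0445 in place of 2.73e-07. Without hypidone 7 the log2 fold changes were 2.41 for Thbs1, 1.46 for Col1a1, 0.73 for Col6a1, 1.86 for Ccr2, 1.35 for Lyz2 and 0.61 for Serping1, without hypidone 2 that of Ccl4 was 1.48, and without control 5 that of Htr1a was -0.03. Lists not called with all libraries but called without control 5 were choroid plexus, cerebellar neuron and homeostatic microglia genes, higher at an adjusted p of 0.000370, 0.000365 and 0.0478, and interferon response genes, lower at 0.00207. The choroid plexus median was 0.77 without control 5 and -1.70 with it.

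Some of the genes named here lie, on the mm10 assembly with GENCODE M21 models, on chromosome 7 at 141455198 to 141460743 on the plus strand (Pnpla2), chromosome 4 at 11156431 to 11174379 on the plus strand (Trp53inp1), chromosome 15 at 74669083 to 74672570 on the minus strand (Arc), and chromosome 5 at 104435118 to 104441050 on the plus strand (Spp1). Sgk1 lies on chromosome 10 at 21882184 to 21999903 and Idi1 on chromosome 13 at 8885501 to 8892451, both on the plus strand. Gfap lies on chromosome 11 at 102887336 to 102900912 on the minus strand. All are annotated as protein-coding.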

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

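The counts of called genes depended on the tool, the libraries and the fit. For MCAO against control, DESeq2 called 2373 higher, limma voom 3645 higher and 3783 lower, a fit of only the 2 groups 345 and 337, and a minimum 2-fold change 869 and 531. For hypidone against MCAO, DESeq2 called 1845 and 2166, voom 3916 and 3715, and the minimum fold 481 and 572. For hypidone against control, DESeq2 called 1 higher gene, and a fit of the 2 groups with control 5 left out, chosen after seeing the data, called 1. The cause was not tested. Fewer libraries leave fewer degrees of freedom, yet without MCAO 4 the counts for MCAO against control rose to 2357 and 1918. The shared spread takes in the hypidone group, whose biological coefficient of variation was 14.5% against 41.7% within MCAO. Control and MCAO share title numbers, which the labels do not describe as a pairing. Same-numbered libraries deviated together by 0.118, 0.123 and -0.0421 (correlation across genes), and differently numbered ones by -0.151 to 0.124. These values cannot decide whether the libraries were paired. With a replicate block 0 genes were called higher and 0 lower, while 21 of 21 lists were kept. No paired fit was possible for the hypidone group, which shares no number.

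Leaving out 1 library gave 480 to 2357 higher and 594 to 1918 lower genes for MCAO against control, 315 to 1752 and 233 to 2123 for hypidone against MCAO, and 12 to 23, 7 to 20 and 15 to 21 called lists for the 3 comparisons in the order of the report. Camera with an estimated correlation called 0 lists in each comparison, and fry 5, 4 and 0. Genes called in opposite directions numbered 3482 with DESeq2, 6654 with voom, 646 with 2-group fits, 896 at a 2-fold minimum, and 541 to 3452 without 1 library. The covariance of fold changes was -1.18 without a filter, -0.620 at a CPM of at least 1 in 3 samples, and -1.10 to -0.688 without 1 library. The shared MCAO libraries alone make it negative, at a mean of -0.145 in the simulated sets, so its sign tests nothing.

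Signs turned for few named genes, none of them called. When single libraries were left out, Aif1 ranged from -0.30 (without MCAO 5) to 1.47 in MCAO against control and from -1.28 to 0.49 (without MCAO 5) in hypidone against MCAO, where voom gave 0.29. In hypidone against control, C1ql2 ranged from -6.85 to 0.0974 (without control 5), Spink8 from -7.49 to 0.31 (without control 5), and Gfap from -0.21 (without control 6) to 1.22 (without control 5). The 2-group fit without control 5 gave 0.10 for C1ql2. Counting each named gene once per alternative, 521 values for MCAO against control kept direction and side of the threshold, 85 lost the call, 2 gained it and 1 turned sign; for hypidone against MCAO these were 559, 70, 2 and 2, and for hypidone against control 405 kept and 6 turned. Depth limits Tnf, Il6, Slc6a4 and Il1b.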

Other observations

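In this part the pathway tests and the tests of library depth, neuronal share, added hippocampal tissue, exchanged labels and added immune cells were chosen only after the result was seen. The authors' deposited table annotates pathways, which were tested with camera. Of 313 pathways, 45 were higher and 10 lower with MCAO, 7 higher and 14 lower with the drug against MCAO, and 44 higher and 5 lower with the drug against control, none with an estimated correlation, where the lowest adjusted p was 0.713, 0.850 and 0.697. Lysosome genes rose in 40 of 117 cases and fell in 2 with MCAO, with Galc, which degrades myelin lipids, up by 1.04 ± 0.17, and fell in 29 cases and rose in 1 with the drug. JAK-STAT genes rose in 26 of 108 cases, among them the feedback inhibitor gene Socs3 at 3.26 ± 0.52, and fell in 4 with MCAO, and fell in 20 and rose in 4 with the drug.

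Retrograde endocannabinoid signalling was lower with MCAO, 19 of 132 genes falling and 6 rising, and higher with the drug, 19 rising and 4 falling. The GABA receptor gene Gabra2 fell by 1.85 ± 0.18 with MCAO and rose by 1.65 ± 0.18 with the drug, and the release site gene Rims1 fell by 1.77 ± 0.29 and rose by 1.85 ± 0.29. Bdnf fell by 2.63 ± 0.46 and Vgf by 1.70 ± 0.26 with MCAO, and rose by 2.63 ± 0.46 and 1.87 ± 0.26 with the drug, the first a growth factor gene and the second that of a neuropeptide precursor. Their neurotrophic list had 1 of 10 genes higher and 3 lower with MCAO, 3 higher and 1 lower with the drug, and was not called (adjusted p = 0.236 and 0.295).

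MCAO libraries spread widely in glial, immune and matrix genes, MCAO 5 exceeding MCAO 4 by 4.18 log2 units in macrophage genes and 3.82 in matrix genes. A difference in depth is argued against, since the total of MCAO 5 was 0.953 of that of MCAO 4. A lower share of neurons alone would raise all other cell types alike, yet list differences spanned 4.03 log2 units, with resting astrocytes at 0.15. Lesion size or the region sampled may differ between these samples, and no biological explanation was tested because the design names no group within MCAO.

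Control 5 held hippocampal genes above every other library for 8 of the 9 tested list members. The 6 upper-layer cortex genes chosen after the data were seen had a median of -2.76 relative to the other controls, and striatal genes -0.54, so tissue with more hippocampus is a candidate explanation. For an exchange of labels with an MCAO library, 2 bounds set to exclude it were not met. Control 5 lay on the control side for 70% of 50 genes picked without it, where over 90% was asked. Among 50 genes picked without control 5 and the MCAO library in question, MCAO 4, 5 and 6 lay on the MCAO side for 62%, 70% and 92%, where over 75% was asked of each. Control 5 lay on the MCAO side for 32%, 22% and 28% of these genes, so by this count no MCAO library was nearer the controls than control 5. On the first principal component, which uses no labels, control 5 was at -22.7 and the MCAO libraries between 10.95 and 103. With control 5 exchanged for MCAO 4, 5 or 6 the fit called 81, 0 and 0 genes, against 3015 with the labels as given. The first component and these fits argue against an exchange, which the unmet bounds alone did not exclude. Glucocorticoid genes had a mean log2 CPM of 5.66 in control 5, 5.51 and 5.14 in controls 4 and 6, and 6.83 to 7.25 in MCAO. That list was chosen after its separation under the given labels was seen, so its levels cannot decide on an exchange. No biological explanation was tested, since the design gives none.

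The last pattern is the change shared by all 3 MCAO libraries, including the glucocorticoid, sterol and p53 lists, that lay nearer the control level with the drug. Sterol genes lay 0.71 to 1.27 log2 units below the control mean in MCAO, 0.24 and 0.26 below it in hypidone 2 and 7, and 0.06 above it in hypidone 8. Over all tested genes, shared MCAO libraries do not account for all of the opposite changes. The covariance stayed at or below -0.276 in all 6 divisions with no library on both sides. It was not computed for the genes of this pattern alone, so for them it does not decide. A trend on gene length is argued against, the glucocorticoid median being 1.61 after its removal and 1.75 before. More immune and glial cells in MCAO tissue could be weighed only in MCAO 4, by comparing single libraries with standard errors over genes. Such errors do not measure the spread between samples. None of 10 immune and glial lists lay over 2 standard errors higher in MCAO 4 than in hypidone 7 or 8. Against hypidone 2 resting astrocyte genes did, by 0.34 ± 0.16. Activated microglia differed from hypidone 7 by -0.11 ± 0.21 and reactive astrocytes by -0.05 ± 0.25 log2 units (SE over genes). Yet the glucocorticoid list was higher in MCAO 4 than in hypidone 7 by 1.60 ± 0.43 and the p53 list by 0.58 ± 0.26, and the sterol list lower by 0.54 ± 0.17. In MCAO 5 and 6 activated microglia lay 3.99 and 2.12 log2 units above the control mean, and there this explanation stays open. An earlier test was undecided, the change in MCAO 4 being 0.63 of that in MCAO 5 for sterol genes and 0.79 for glucocorticoid genes, where 0.75 was asked of both. The tissue sampled, the hemisphere, the time of sampling and any library batch stay open and untested, and could follow the MCAO group exactly.

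A hypothesis came from Pnpla2, Pik3ip1, Sesn1 and Ddit4, picked after their values were seen (edgeR adjusted p between 0.000224 and 0.00727 with MCAO). It was that genes induced by FOXO factors, as after loss of growth factor signalling, may rise in MCAO. The other FOXO target genes in a list written before their values were seen had a median log2 fold change of 0.28 over 21 tested genes, 6 higher and 0 lower (camera p = 0.0150, or p = 0.0375 with an estimated correlation, unadjusted). With the drug the median was -0.26, with 3 lower. Klf15, also induced by glucocorticoids, rose by 1.35 ± 0.18 and Cited2 by 1.02 ± 0.15, while Sod2 and Cat, classical targets, had -0.32 ± 0.12 and -0.33 ± 0.22, neither called, so the data are only in part consistent with this hypothesis.

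Other divisions of the 6 libraries into 3 and 3 were too few, 10 per comparison, for a share under 0.05. For MCAO against control the real division called 3015 genes and the highest other 81, and for hypidone against MCAO 2437 and 0, so 1 of the 10 reached the real count in each. For hypidone against control all 10 called 0.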
